A study of Mus musculus with 22 samples.

How the data were processed

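H/ACA small nucleolar RNAs (snoRNAs), which guide the conversion of uridine to pseudouridine in ribosomal and other RNAs, were measured in mouse cells with a custom code set on the nCounter, an instrument that counts colour-coded probes hybridised to RNA without amplification. Total RNA was extracted with Trizol, treated with DNase and purified on columns, per the labels' protocols. The 22 samples fall into 7 groups: spermatogonial stem cells (SSC, n = 4), NIH3T3 fibroblasts (n = 3), RAW264.7 macrophages (n = 3), embryonic stem cells (ESCs) of a puromycin selection line at day 0 of differentiation (n = 3), cardiomyocytes derived from them at day 16 (n = 3) and 2 sets of 3 ESC samples from a retinoic acid experiment. For these last 6 samples the label fields contradict each other. Title, source and treatment field call one set (set A) treated with retinoic acid while its description says untreated at time 0, and the other set (set B) is titled as plain ESCs while its description says retinoic acid at time 6. The division into 2 sets is the same in every field, so sets were compared as set B against set A, and the direction of treatment is left open. Myoblast samples named in the series design were not analysed here.

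The deposited table holds 72 features as a non-negative signal, here called normalized counts, and no source used here states how the authors normalized it, which software they used or how background was treated. Within every sample 100% of the deposited signal values were whole multiples of 1 step (tolerance 0.02), between 0.900 and 1.22, so the values are whole counts times 1 factor per sample. What set the factor is not given in the sources used here, and no reference gene or control probe is in the table, so a shift of all snoRNAs together cannot be checked against other RNAs. Totals per sample ran from 1045169 to 1668320 normalized counts, or 932203 to 1547009 whole counts. Counting error is small at this depth: in every group each pair of replicates differed by more than counting noise (lowest chi-square per degree of freedom 18.3), so no sample was counted as the same library deposited again, and the spread between samples sets the precision. Repeat extractions or hybridisations of 1 sample would also differ by more than counting noise, so whether SSC samples 2, 3 and 4 are such repeats stays open. The labels do not say whether replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Of the 72 features, 5 are blank in the 10 samples of SSC, NIH3T3 and RAW264.7 and hold 6.59 to 101.39 normalized counts in the other 12. The table thus has 2 parts, and ESCs at day 0 lie in a different part than the other 3 cell types; whether the parts were run or normalized separately is not given in the sources used here.

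Features are listed by transcript accession with an offset. Through the RefSeq table of assembly GRCm38.p6, 34 matched a gene symbol, and all 34 lie within another gene, taken as host gene from the same table. The other 38 carry transcript IDs that the table does not pair with a name and are named by ID. No genome build is named for the data, so no coordinates are given. Probes for near-identical snoRNA copies may capture each other's RNA.

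Tests used log2(value + 1) without further scaling, so differences are on that scale. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, Benjamini-Hochberg adjustment over the features tested, threshold 0.05). The 4 cell types (13 samples, 67 features without blanks) shared 1 model, with a moderated F-test and a contrast of each type against the mean of the other 3. These 4 contrasts are not independent: a feature low in 1 type lowers the mean that each other type is compared with. Cardiomyocytes against day 0 and set B against set A were fitted on their own 6 samples over 72 features, and the difference between both effects on 12 samples. Agreement of the effects was measured by Pearson's r and Spearman's rho across snoRNAs with a permutation test (100000 resamples) that treats snoRNAs as exchangeable. snoRNA lists fixed before the data were examined, by rRNA target and by host gene class, were tested with limma's fry. Only lists with at least 4 measured members were tested, adjusted over the lists of a comparison. The alternative was camera with an estimated correlation. Camera compares a list with the other features and fry does not. Values given with an estimated correlation are from camera and answer a different question than fry. Host lists were fixed from symbols: that of ribosomal protein hosts lacks Snora33 (host Rps12), and both it and the Snhg list lack Snora78, which the table places in Rps2 and in Snhg9. Guides of 18S rRNA had 7 measured members of 23, guides of 28S rRNA 14 of 26, snoRNAs hosted in non-coding Snhg genes 7 of 12 and those hosted in ribosomal protein genes 10 of 15. Other lists had fewer: translation factor hosts 3, chaperonin hosts, 5.8S guides, guides of both rRNAs and the U17 type 1 each, and hosts Taf1d and Dkc1 0.

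Named features were chosen by a rule set before the data were examined: for each contrast the 10 with the largest difference in each direction among those past the threshold whose single samples did not overlap between the groups, for the F-test the 10 with the largest and 5 with the smallest range of group means among features above the median level, and everywhere Snora73a, Snora74a, Snora69, Snora64 and Snora36b. Snora27, Snora73b, Snora72 and Snora36a were also fixed but match no named feature, and the panel holds no reference feature. Fewer than that are named where fewer qualified, not every feature that qualified is printed, features known by ID only are mostly given as counts, and others are named where said. In simulated data with the real levels and spread and 20 changed features in each of 50 runs, the fits recovered 97.8% of 2-fold and 100% of 4-fold changes for SSC against the rest (67 features), 65.2% and 90.6% for cardiomyocytes (72 features), 69.2% and 86% for set B against set A (72 features) and 49.2% and 80% for the difference of effects (72 features). False calls made up 7.1%, 6.5%, 7.4% and 8.1% of calls in these 4. A simulated list of 7 moved members was called in 50 of 50 runs and an unmoved one in 2 of 50. Noise was drawn separately for each feature, without a shift shared by a sample or group. In the real data a common axis held 54.7% of the variance within groups. The simulated rates and list results may therefore not carry over to the real data.

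Alternatives set before the data were examined were pseudocounts of 0.5 and 10, a minimum of 20 in at least 3 samples, median centring, quantile normalization, limma with trend and robust settings, replicate number as a block (for set B against set A also with the numbers of the titles), the sign of the retinoic acid effect turned, all 7 groups in 1 fit, SSC samples 2, 3 and 4 averaged (their descriptions share a number) and each replicate left out. Chosen after seeing the data were voom on the whole counts, centring each sample on its mean log2 value, the cell type fits without the ESC samples, and leaving out replicate 1 of cardiomyocytes and of set B together. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for tabulation.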

Results

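Expression of H/ACA snoRNAs was profiled in 4 mouse cell types and in 2 models of ESC differentiation, to ask which guide RNAs differ between cell types and which change as stem cells differentiate. SSCs are the self-renewing germ cells of the testis, NIH3T3 is an embryonic fibroblast line and RAW264.7 a macrophage line. ESCs at day 0 and cardiomyocytes at day 16 form the first differentiation model, in which cardiomyocytes were selected with puromycin. The second comprises ESC sets A and B of the retinoic acid experiment. Total normalized counts per sample were lowest in SSCs (1045169 to 1314424) and cardiomyocytes (1137064 to 1317794), and ran from 1323727 to 1668320 in the other groups. Replicates varied most in cardiomyocytes and set B, with median SDs of 0.38 and 0.26 on the log2 scale, against 0.13 to 0.21 in the other 5 groups.

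The first comparison asked which snoRNAs differ between SSCs, NIH3T3, RAW264.7 and ESCs at day 0. Most did: 61 of 67 features passed the moderated F-test, and 37 of these spanned at least 2-fold between the highest and lowest group mean. Snora64, a guide of 28S rRNA encoded in the ribosomal protein gene Rps2, spanned 5.93-fold, from 21622 ± 3676 normalized counts (SD, n = 4) in SSCs to 3763 ± 1396 (n = 3) in RAW264.7 (adjusted p 9.3e-09). Snora36b, a guide of 18S rRNA, spanned 5.59-fold, from 1647 ± 337 in RAW264.7 to 294 ± 58 in ESCs (n = 3 each, adjusted p 8.5e-09). Snora81, hosted in the translation factor gene Eif4a2, was highest in SSCs and lowest in RAW264.7 with a 4.08-fold range. Snora26, Snora24, Snora73a, Snora33 and Snora70 had ranges of 2.90, 2.84, 2.70, 2.37 and 2.12-fold, and all 5 were lowest in SSCs. Snora73a (U17), which acts in cleavage of the rRNA precursor rather than as a guide, had 50632 ± 7036 normalized counts in SSCs and 136433 ± 18210 in ESCs.

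Few snoRNAs were level across the cell types. Among features above the median level, the smallest ranges were those of 2 IDs (1.05 and 1.23-fold), Snora17 (1.37-fold), Snora3 (1.39-fold) and Snora21 (1.42-fold). Snora17 and Snora21 still passed the F-test (adjusted p 0.0073 and 0.011), but Snora17 did not under quantile normalization (adjusted p 0.29) and Snora21 did not without the ESC samples (adjusted p 0.14). Snora3 did not pass (adjusted p 0.19). Snora69, a guide of 5.8S rRNA, had a range of 1.21-fold (adjusted p 0.65). Of the 61 features that passed, 23 were highest in SSCs and another 23 were lowest there. ESCs lie in the part of the table without blanks and the other 3 types in the part with blanks. Without ESCs, 59 of 67 features passed.

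SSCs differed from the mean of the other 3 types in 56 of 67 features, 29 higher and 27 lower. Snora64 was 3.48-fold higher (log2 difference 1.80 ± 0.15 SE, adjusted p 5.4e-08) and Snora30, a guide of 28S rRNA hosted in Srcap, was 2.87-fold higher (1.52 ± 0.13), at 13914 ± 2635 normalized counts against 3726 ± 302 in NIH3T3. Snora15 was 1.46-fold higher. Snora43 showed the largest decrease of a named snoRNA, 3.90-fold (log2 difference −1.96 ± 0.13, adjusted p 5.4e-09), with 3223 ± 712 normalized counts in SSCs and 16361 ± 2836 in ESCs. Snora24, Snora73a and Snora33 were 2.32, 2.26 and 2.02-fold lower. In all of these the 4 SSC samples lay beyond all 9 others. Snora36b was 1.52-fold higher and Snora74a 1.26-fold lower with overlapping samples. Neither passed under quantile normalization (adjusted p 0.24 and 0.62) or without the ESC samples (adjusted p 0.20 and 0.12). Snora74a also did not pass after median centring (adjusted p 0.055) or with SSC samples 2, 3 and 4 averaged (adjusted p 0.058). Snora69 did not pass (log2 difference −0.15 ± 0.17).

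All 7 measured members of the list of Snhg-hosted snoRNAs were lower in SSCs, 7 of 7 also when adjusted over the list alone. Their median log2 difference was −0.67 (fry adjusted p 1.3e-05). In camera with an estimated correlation, which compares a list with the other features, the adjusted p was 0.62. Besides Snora43, Snora24 and Snora73a the members were Snora44, Snora16a, Snora17 and Snora74a. The call of Snora74a was lost in the settings given above. Snora78, which lies in both Rps2 and Snhg9, is in neither host list and was 1.52-fold higher in SSCs with overlapping samples (adjusted p 0.0066); it was singled out after its values were seen. Of the 10 hosted in ribosomal protein genes 6 were higher, among them Snora64, and Snora70 was lower (fry adjusted p 0.0074; adjusted p 0.62 with an estimated correlation). Guides of 18S rRNA had 4 of 7 members lower and 2 higher (fry adjusted p 0.0028, down; adjusted p 0.62 with an estimated correlation). The 14 guides of 28S rRNA moved both ways, 8 higher and 4 lower (fry adjusted p 0.12, or 0.012 after median centring; adjusted p 0.62 with an estimated correlation). Adjusted over the list alone, these 3 lists gave the same counts. Of the 3 snoRNAs hosted in translation factor genes, a list too small to test, 1 was higher and 1 lower in each of SSC, RAW264.7 and ESC, 1 higher and 2 lower in NIH3T3, 0 passed at day 16 against day 0, and 1 (Snora28) was higher in set B.

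In NIH3T3, 40 features differed from the mean of the other types. Snora47, hosted in Zbed3, was 3.67-fold higher (log2 difference 1.88 ± 0.13, adjusted p 1.8e-08), at 2037 ± 84 normalized counts against 234 ± 31 in ESCs. Snora24, a guide of 18S rRNA, was 1.73-fold higher and Snora2b 1.47-fold higher. Snora41, hosted in the elongation factor gene Eef1b2, was 2.46-fold lower (−1.30 ± 0.32) and Snora75, hosted in the nucleolin gene Ncl, 1.93-fold lower (−0.95 ± 0.19). Snora5c, Snora15, Snora62 and Snora52 were 1.73, 1.66, 1.54 and 1.47-fold lower. Among the fixed snoRNAs, Snora64 and Snora36b were 2.74 and 2.39-fold lower with some overlap, Snora73a and Snora74a were 1.53 and 1.48-fold higher, and Snora69 did not pass. The median log2 difference over all features was −0.28, and the split of calls moved with it, from 9 higher and 31 lower to 17 and 18 after median centring.

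Under quantile normalization Snora24 (log2 difference 0.28), Snora75, Snora52 and Snora73a did not pass (adjusted p 0.11, 0.060, 0.079 and 0.079), and Snora75 did not with all 7 groups in the fit (adjusted p 0.19). Of the 7 Snhg-hosted snoRNAs 3 were higher (Snora24, Snora73a and Snora74a) and 0 lower (fry adjusted p 0.014, camera with an estimated correlation adjusted p 0.51). SSCs, where all 7 were lower, are part of the mean compared with here, so this is not independent of the SSC result. Guides of 18S rRNA had 3 lower and 2 higher (fry adjusted p 0.012, down) and ribosomal protein hosts 3 of 10 lower (fry adjusted p 0.014). Both calls were lost after median centring (fry adjusted p 0.87 and 0.85). Neither list passed in camera with an estimated correlation (adjusted p 0.91 for each). Guides of 28S rRNA had 5 of 14 lower and 1 higher (fry adjusted p 0.072). Adjusted over the list alone, all 4 lists gave the same counts.

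RAW264.7 macrophages differed in 31 features, 23 higher and 8 lower. Snora36b was 3.95-fold higher (log2 difference 1.98 ± 0.14, adjusted p 3.8e-08). Snora70, a guide of 18S rRNA hosted in Rpl10, was 1.65-fold higher, with 46984 ± 2575 normalized counts against 22348 ± 3335 in SSCs, and Snora31, hosted in Tpt1, was 1.40-fold higher. Snora78 was 2.04-fold lower (−1.03 ± 0.20), and so with overlapping samples were Snora64, which lies in the same host gene Rps2 (3.08-fold), and Snora74a (1.58-fold). Snora73a (−0.17 ± 0.12, adjusted p 0.28) and Snora69 (0.22 ± 0.18) did not pass. Snora73a passed after median centring (−0.33, adjusted p 0.045) and when centred on the mean log2 value (−0.35, adjusted p 0.016), and was 0.0797 without the ESC samples (adjusted p 0.63). Guides of 18S rRNA had 3 of 7 members higher (Snora36b, Snora70 and Snora28) and 0 lower (fry adjusted p 2.6e-05; adjusted p 0.76 with an estimated correlation). Snhg-hosted snoRNAs (1 higher, 1 lower), ribosomal protein hosts (2 higher, 1 lower) and guides of 28S rRNA (2 higher, 2 lower) did not pass, and their counts were the same adjusted over the list alone. For guides of 28S rRNA the median log2 difference was 0.08 while the test pointed down. The median over all features was 0.20, and centring on the mean log2 value gave 16 higher and 10 lower.

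ESCs at day 0 differed from the other types in 37 features, 20 higher and 17 lower. Snora43, a guide of 28S rRNA hosted in Snhg7, was 2.26-fold higher (log2 difference 1.18 ± 0.14, adjusted p 7.2e-06), Snora26, hosted in the non-coding gene Dancr, 2.16-fold higher (1.11 ± 0.15) and Snora44, hosted in Snhg12, 1.59-fold higher. Snora47 was 4.88-fold lower (−2.29 ± 0.13, adjusted p 1.1e-09), the lowest of the 4 types in all 3 samples. With overlapping samples Snora64, Snora73a and Snora74a were 2.43, 1.67 and 1.34-fold higher and Snora36b was 2.51-fold lower. Snora44 did not pass under quantile normalization (adjusted p 0.056) and Snora74a not after median centring (adjusted p 0.11), and Snora69 did not pass in any scaling run. Snhg-hosted snoRNAs had 5 of 7 members higher and 0 lower (fry adjusted p 0.0026, camera with an estimated correlation adjusted p 0.95). Their counts were the same adjusted over the list alone. The mean compared with includes SSCs, where all 7 were lower, so this too is not independent of the SSC result. Guides of 18S rRNA (2 higher, 2 lower), guides of 28S rRNA (5 and 4) and ribosomal protein hosts (2 and 3, or 1 and 3 adjusted over the list alone) did not pass. After median centring guides of 18S rRNA and ribosomal protein hosts passed (fry adjusted p 0.000316 and 0.0267), but not with an estimated correlation (adjusted p 0.95 for each). For guides of 18S rRNA the median log2 difference was 0.07 while the test pointed down. Median centring gave 16 higher and 21 lower. Table part and cell type cannot be told apart in this contrast.

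**Figure D1:**
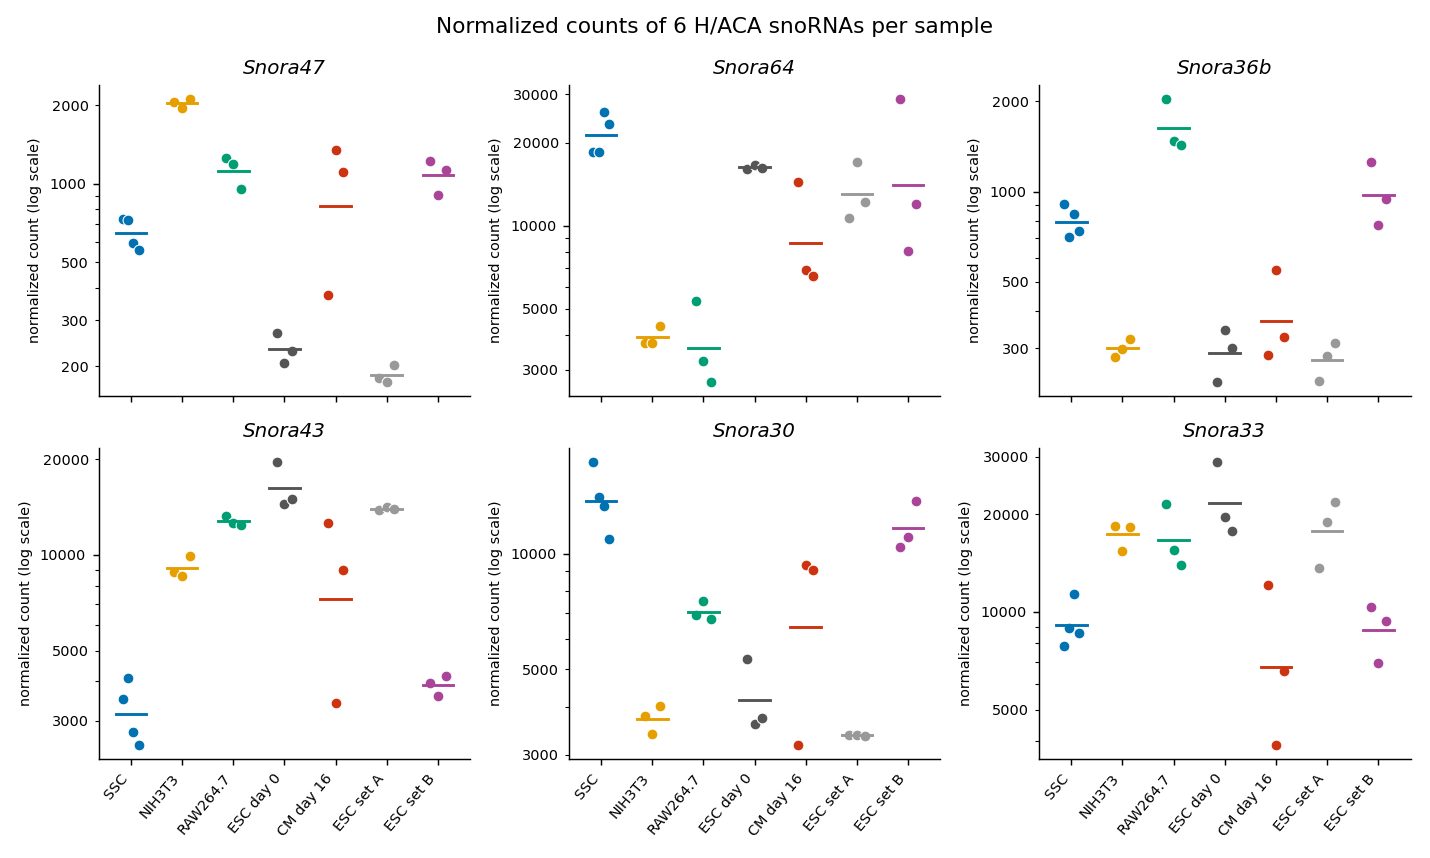
Normalized counts (log axis) of 6 snoRNAs in the 22 samples, 1 point per sample and a line at each group's mean log2 value. Snora47 lies between 206 and 268 in the 3 ESC day 0 samples, between 375 and 1343 in cardiomyocytes, and between 1947 and 2113 in NIH3T3. Snora43 lies between 2528 and 4086 in SSCs and between 14427 and 19617 in ESCs at day 0.

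The second comparison asked which snoRNAs change as ESCs become cardiomyocytes. At day 16, 22 of 72 features passed the test, 1 higher and 21 lower. The 21 include Snora35, which is blank in the other part of the table. It held only 19.86 to 43.05 normalized counts, and how background was treated is not known. Snora47 was the 1 that rose, 3.53-fold (log2 difference 1.82 ± 0.48, adjusted p 0.034), from 234 ± 31 to 944 ± 506 normalized counts (SD, n = 3 each). Snora33, a guide of 28S rRNA hosted in Rps12, fell 3.18-fold (−1.67 ± 0.43, adjusted p 0.033), from 22084 ± 5971 to 7538 ± 4191. Snora3, Snora15, Snora34, Snora44 and Snora24 fell 2.51, 2.44, 2.37, 2.29 and 2.28-fold, each with all 3 cardiomyocyte samples below all 3 ESC samples. Samples did not overlap in 38 of 72 features, where chance gives 10%. Snora74a also fell (−0.68 ± 0.16, adjusted p 0.032). Snora64 did not pass (−0.91 ± 0.32, adjusted p 0.070), nor did Snora69, Snora36b and Snora73a, which had 131134 ± 2678 normalized counts at day 16.

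These decreases stand against a median log2 difference of −0.51 over all 72 features, and total counts were also lower at day 16. Centred on each sample's mean log2 value, limma called 0 features (22 at an unadjusted p under 0.05), with Snora47 at 2.31, Snora33 at −1.18 and Snora24 at −0.70. Median centring gave 5 higher and 1 lower, with Snora47 at 2.63 (adjusted p 0.013) and Snora74a at 0.14, and quantile normalization 3 higher and 0 lower, with Snora47 at 1.82 (adjusted p 0.079). With replicate number as a block 8 features passed, all lower, and Snora47 (adjusted p 0.061) and Snora74a (adjusted p 0.094) did not. With all 7 groups in the fit 39 passed, 4 higher and 35 lower, Snora64 among them (adjusted p 0.047). Leaving out cardiomyocyte replicate 1 gave 34 calls, Snora64 and Snora69 among them (adjusted p 0.0057 and 0.048). Leaving out replicate 2 gave 7, and Snora47, Snora33, Snora3, Snora44 and Snora74a did not pass (adjusted p 0.084, 0.071, 0.084, 0.056 and 0.056), while limma called 0 without replicate 4 (30 at an unadjusted p under 0.05) and without ESC replicate 1, 2 or 4 (29, 23 and 21).

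By list, Snhg-hosted snoRNAs had 5 of 7 members lower (Snora44, Snora24, Snora74a, Snora16a and Snora17; fry adjusted p 0.0037), guides of 18S rRNA 3 of 7 (Snora15, Snora44 and Snora24; fry adjusted p 0.00012), guides of 28S rRNA 5 of 14 (fry adjusted p 0.010) and ribosomal protein hosts 2 of 10, or 0 adjusted over the list alone (fry adjusted p 0.013). None of the 4 had a member higher, and the first 3 gave the same counts adjusted over the list alone. In camera with an estimated correlation none of the 4 passed (adjusted p 0.87 for the first 3 and 0.88 for the last). Camera asks whether a list moved apart from the other features, a different question than that of fry. After median centring all 4 lists changed direction and did not pass in fry (adjusted p 0.89, 0.72, 0.50 and 0.29).

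The third comparison concerned retinoic acid, as set B against set A. Of 72 features 33 differed, 21 higher in set B and 12 higher in set A. The 12 include an ID that is blank in the other part of the table and held only 10.99 to 101.39 normalized counts. The samples of the sets did not overlap in 40 features, the 33 among them, where chance gives 10% of features. Snora47 was 5.77-fold higher in set B (set B minus set A 2.53 ± 0.15, set A minus set B −2.53, adjusted p 0.00013), with 1087 ± 162 normalized counts in set B and 186 ± 15 in set A. Snora36b and Snora30 were 3.53 and 3.46-fold higher in set B (1.82 ± 0.22 and 1.79 ± 0.13, or −1.82 and −1.79 with the sign turned). Snora28, a guide of 18S rRNA hosted in the initiation factor gene Eif5, was 2.26-fold higher in set B (69212 ± 9551 against 30460 ± 1898). Snora43 was 3.59-fold higher in set A (set B minus set A −1.84 ± 0.10, sign turned 1.84, adjusted p 0.00013), at 13976 ± 127 normalized counts in set A and 3902 ± 293 in set B. Snora33, Snora52 and Snora16a were 2.02, 1.95 and 1.40-fold higher in set A. Snora33 and Snora52 did not pass under quantile normalization (adjusted p 0.054 for each) and Snora16a not after median centring (adjusted p 0.42) or mean centring (adjusted p 0.072). With replicate number as a block, from the descriptions or from the titles, Snora33 (adjusted p 0.079 and 0.080) and Snora16a (adjusted p 0.11 and 0.089) did not pass. Without set A replicate 3 or 4, neither Snora33 (adjusted p 0.075 and 0.0595) nor Snora16a (adjusted p 0.072 and 0.0595) passed. Snora33 also did not without set B replicate 3 (adjusted p 0.051), and Snora16a not without set A replicate 1 (adjusted p 0.057), while Snora47, Snora36b, Snora30, Snora28 and Snora43 passed under every alternative run. Snora73a, Snora74a, Snora69 and Snora64 did not pass. Which set received retinoic acid stays open, because the label fields contradict each other.

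Of the Snhg-hosted snoRNAs 3 of 7 were higher in set A (Snora43, Snora16a and Snora44) and 0 in set B (fry adjusted p 0.0014; adjusted p 0.46 with an estimated correlation and 0.33 after median centring). Guides of 18S rRNA (3 higher in set B, 1 in set A), guides of 28S rRNA (3 and 3) and ribosomal protein hosts (3 and 1, or 2 and 1 adjusted over the list alone) did not pass, and the first 3 lists gave the same counts adjusted over the list alone. After median centring the guides of 18S rRNA passed (fry adjusted p 0.0311), but not with an estimated correlation (adjusted p 0.86). For guides of 28S rRNA the median log2 difference was 0.14 while the test pointed down. The median of all features, 0.16 as set B minus set A, was 0.06 when centred on the mean log2 value and 0.31 after median centring. The split of calls moved with scaling, to 10 and 10 under quantile normalization and 12 and 13 when centred on the mean log2 value. Replicate number as a block gave 14 features with the numbers of the descriptions and 15 with those of the titles. Without set A replicates 1, 3 or 4, limma called 18, 17 and 21 features.

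Effects in both models were then compared snoRNA by snoRNA. Across 72 features, which are not independent replicates, cardiomyocytes minus day 0 correlated with set B minus set A (Pearson's r 0.764, Spearman's rho 0.708, permutation p 1e-05 for each, the smallest the resampling can give). With set A minus set B the values were −0.764 and −0.708. Signs matched in 43 of 72 features. Passing in both were 6 features, against 0.292 expected higher in both and 3.5 lower in both from independent lists: Snora47, higher at day 16 and in set B, and Snora33, Snora16a, Snora44 and 2 IDs, lower at day 16 and in set B. Neither contrast shares samples with the other.

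Differences between both effects depended on the reading of the labels. Taking set B minus set A, 17 features passed, all more negative in the cardiomyocyte model. Snora5c (difference −1.11 ± 0.26, adjusted p 0.024), Snora36b (−1.46 ± 0.39) and Snora74a (−0.75 ± 0.17) were among these 17. The median difference over all 72 features was −0.64 and 11 were positive, so most features shifted the same way. With the sign of the retinoic acid effect turned, 39 passed, 15 positive and 24 negative. Among them were Snora47 (4.35 ± 0.55), Snora43 (−3.00 ± 0.54), Snora33 (−2.69 ± 0.54), Snora36b (2.18 ± 0.39) and Snora16a (−1.16 ± 0.19). Snora16a did not pass after median centring (−0.20, adjusted p 0.74), and Snora36b not under quantile normalization (1.58, adjusted p 0.054). The first count fell to 0 under median centring, quantile normalization and mean centring (8, 8 and 10 at an unadjusted p under 0.05 in limma). With replicate number as a block the first count was also 0, and Snora5c, Snora36b and Snora74a had an adjusted p of 0.13 in limma. It fell to 1 without set A replicate 1, set A replicate 3 or ESC replicate 2, to 4, 8 and 10 without set B replicate 1, set B replicate 3 and set A replicate 4, and to 7 and 5 without ESC replicates 1 and 4.

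**Figure D2:**
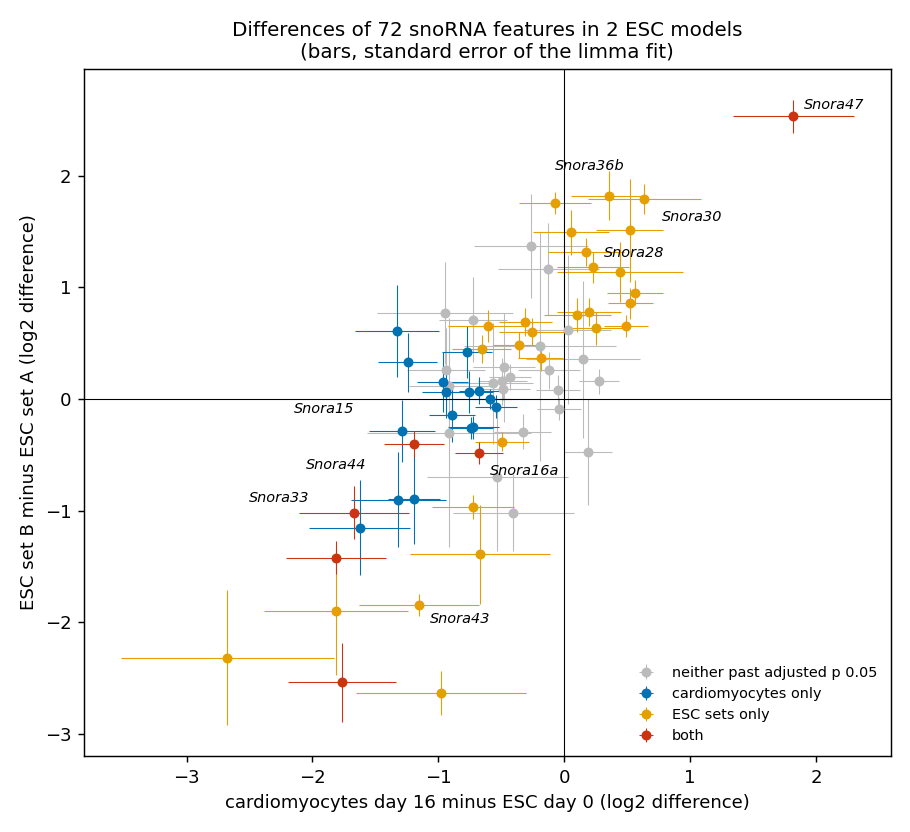
Log2 difference of each of 72 snoRNA features between cardiomyocytes at day 16 and ESCs at day 0 (horizontal axis) and between ESC set B and set A (vertical axis), with standard errors of the limma fits as bars and colours for features past an adjusted p of 0.05. Snora47 lies at 1.82 and 2.53, and Snora33 at −1.67 and −1.02.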

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

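The tests of the spread between replicates and of the scaling factors were chosen after the result was seen; the counts over other splits of the samples and both tests of the correlation were set before. In SSCs, the group of 4 samples, 0 of 53 values tested had a sample far from the others by Dixon's criterion at 95%.

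The cardiomyocyte effect and set B minus set A differed in 17 features by a test of the difference itself. Of these, 8 passed under both readings of the labels, and 5 of the 8 fall under the naming rule in a differentiation comparison. The rest of the 8 include Snora35, at only 19.86 to 43.05 normalized counts. The differences of these 5 were −0.75 for Snora74a, −1.46 for Snora36b, and −1.44, −1.82 and −1.14 for 3 features known by transcript ID only. None of the 5 passed after median centring (−1.16 to −0.0862), quantile normalization (−0.94 to −0.15) or centring on the mean log2 value (−1.23 to −0.16), where all 5 kept their sign and were smaller in size. None passed with replicate number as a block either, where the differences were the same (adjusted p 0.13 for each), and the count over all features fell to 1 without set A replicate 1, set A replicate 3 or ESC replicate 2. With the sign turned the difference became positive for Snora36b (2.18) and for the 3 IDs.

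For 4 cell type counts 1 of 100 splits, the real one, gave as many features. These were the F-test (61, highest other 7), SSC (56, highest other 40), NIH3T3 (40, highest other 22) and ESCs (37, highest other 13). The counts thus exceeded those of random groupings of these samples. The splits exchange samples as independent units, but replicates may be technical and some SSC samples may be repeats. Chance differences between separate cultures or animals are therefore not excluded. For RAW264.7 the real split was also the 1 of 100 with as many (31, highest other 30), but the margin over the next split is smaller than the range of the real count without single replicates (27 to 34). For cardiomyocytes (22, highest other 0) and set B against set A (33, highest other 0) the 10 splits, of which 1 gave as many, are too few for a share under 0.05. For the difference of effects 3 of 100 splits gave at least 17, and the highest other gave 39. That split exchanges sets A and B as a whole, which is the reading with the sign turned, and the highest of the remaining 98 gave 26. With the sign turned 1 of 100 splits gave as many as the real 39 (highest other 26).

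Replicates of cardiomyocytes and of set B spread along a common axis, the first axis of the deviations within all 7 groups. Both groups had the widest spread and so largely set this axis. It held 54.7% of the variance within groups, and replicate 1 lay at 4.45 in cardiomyocytes and at 4.75 in set B. Far out on the other side lay cardiomyocyte replicate 2 at −3.37 and set B replicate 4 at −4.23. One wrong scaling factor per sample is argued against as the whole cause. Of the variance within both groups, 79.4% was left after centring each sample on its mean log2 value. The share was 88.6% in cardiomyocytes and 70.3% in set B, against 71.1% to 92.5% in the other 5 groups. A part due to scaling, above all in set B, is not excluded. The first axis of variation within the other 5 groups is argued against as the source by correlations of at most 0.165 with it (the smaller of both 0.153). That axis held 39.4% of the variance within those groups. Their other axes were not tried, so a factor that also varies within the other groups stays open. By chi-square per degree of freedom, replicate 1 lay furthest from its replicates in every group except set A. In NIH3T3 its pairs gave 169 and 102 against 18.3. On the common axis replicate 1 lay at −0.92 in SSC, −0.97 in NIH3T3, 0.85 in RAW264.7 and −0.51 in ESCs at day 0. Replicate 1 minus the other replicates correlated at 0.698 across features between cardiomyocytes and set B. A cause tied to replicate number was not tested. Cardiomyocyte replicate 1 may lie partway between day 0 and the other day 16 samples: 25% of its features fell outside the range of the other 5 samples, but so did 25% of those of replicate 4, against 65.3% of those of replicate 2 and 6.94% to 48.6% of those of the ESC samples, and without marker genes on the panel this stays open, as do differences between cultures, which were not tested.

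The lower median at day 16 was also weighed. The authors' scaling factors are argued against as its whole cause, because the median log2 difference was −0.42 in whole counts before the factors and −0.51 after them. A change in RNA input or in total snoRNA content could give the same shift and cannot be separated without reference genes, and a biological decrease with differentiation stays untested.

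The correlation of both effects across features was the third pattern. Both effects correlated with the axis above, at −0.54 for cardiomyocytes and −0.48 for set B minus set A over 67 features. The axis did not carry the correlation of effects. With the axis regressed out of both, r was 0.729 over these 67 features, against 0.764 over 72 features before. Nor did the 6 features called in both carry it, as r was 0.700 without them. The correlation may reflect a response shared by both models, which is a hypothesis from the same data, and its sign depends on which label field of the retinoic acid samples is right.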

How the results depend on the processing

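Mean centring, voom, the fits without the ESC samples and the joint removal of both replicates 1 were chosen after seeing the data. The cell type counts stayed within 1.5 times under every alternative run; leaving out replicates gave 58 to 61 features for the F-test, 51 to 57 for SSC, 31 to 41 for NIH3T3, 27 to 34 for RAW264.7 and 31 to 37 for ESCs. Cardiomyocytes gave 6 features after median centring, 3 under quantile normalization, 8 with replicate number as a block and 39 with all 7 groups in the fit. Centred on the mean log2 value limma called 0 (22 at an unadjusted p under 0.05), and without single replicates 0 to 34. Voom on the whole counts kept the deposited factors, without any centring, and gave 24. Set B against set A gave 20 under quantile normalization, 14 and 15 with the numbers of descriptions and titles as blocks, and 17 to 36 without single replicates. By the numbers of the descriptions, 2 of 6 samples in each model correlated best with their own number. With 3 samples per group this cannot show whether equal numbers pair the samples. The numbers of the titles were not tried in this way. The difference of effects gave 0 under median centring, quantile normalization, the block and mean centring in limma (8, 8, 22 and 10 at an unadjusted p under 0.05). Voom, again with the deposited factors and without centring, gave 20. The count was 39 with the sign turned, 5 without both replicates 1 and 1 to 20 without single replicates. With the sign turned, leaving out single replicates gave 33 to 42. The correlation of effects ran from 0.579 to 0.808 without single replicates and was 0.841 without both replicates 1. Where a left-out replicate leaves 2 samples, fewer samples lower the power; the other causes were not tested.

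Values that changed sign were, by setting: after median centring Snora69 in NIH3T3 (0.20) and cardiomyocytes (0.25), Snora73a (0.77) and Snora74a (0.14) in cardiomyocytes, Snora73a in the difference (0.54) and, with the sign turned, Snora74a (0.36), Snora69 (0.54) and Snora64 (0.17). Under quantile normalization they were Snora69 in NIH3T3 (0.24) and cardiomyocytes (0.30), 1 ID in ESCs (0.17), Snora73a in set B against set A (0) and, in the difference with the sign turned, Snora73a (−0.0892), Snora69 (0.68) and Snora64 (0.16). Under mean centring they were Snora69 in NIH3T3 (0.20), Snora73a in cardiomyocytes (0.45), the difference (0.46) and set B against set A (−0.0189), and Snora74a there (−0.0241). Without the ESC samples Snora73a in RAW264.7 was 0.0797, and with SSC samples averaged Snora69 in ESCs was 0.0196. Without single replicates Snora69 ran from −0.15 to 0.13 in NIH3T3, −0.0230 to 0.39 in RAW264.7, −0.16 to 0.10 in ESCs and −0.40 to 0.55 in set B against set A, where Snora64 ran from −0.40 to 0.51 and Snora74a from −0.0138 to 0.15. Snora73a ran from −0.11 to 0.0581 in cardiomyocytes and −0.0299 to 0.15 in the difference with the sign turned.

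Adjusted p-values of lists after median centring, all from fry: guides of 28S rRNA in SSC 0.0120, NIH3T3 0.845, ESCs 0.155, cardiomyocytes 0.499 and set B against set A 0.395; guides of 18S rRNA in NIH3T3 0.868, ESCs 0.000316, cardiomyocytes 0.723 and set B against set A 0.0311; Snhg hosts in RAW264.7 0.419, cardiomyocytes 0.885 and set B against set A 0.334; ribosomal protein hosts in NIH3T3 0.845, RAW264.7 0.360, ESCs 0.0267 and cardiomyocytes 0.291. Of these, 10 had the opposite direction to the deposited scaling: guides of 28S rRNA in NIH3T3, ESCs, cardiomyocytes and set B against set A, guides of 18S rRNA in NIH3T3 and cardiomyocytes, Snhg hosts in RAW264.7 and cardiomyocytes, and ribosomal protein hosts in RAW264.7 and cardiomyocytes. With an estimated correlation no list passed: SSC 0.621 (18S guides and ribosomal protein hosts) and 0.618 (Snhg hosts), NIH3T3 0.905 (18S guides, 28S guides and ribosomal protein hosts) and 0.514 (Snhg hosts), RAW264.7 0.759 (18S guides, Snhg and ribosomal protein hosts), ESCs 0.948 (28S guides and Snhg hosts), cardiomyocytes 0.874 (18S guides, 28S guides and Snhg hosts) and 0.879 (ribosomal protein hosts), and set B against set A 0.461 (Snhg hosts). Directions were opposite to fry for 18S and 28S guides in NIH3T3, Snhg and ribosomal protein hosts in RAW264.7 and 28S guides in ESCs. Camera compares a list with the other features and fry does not, so the 2 tests ask different questions by construction.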

Other observations

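The test of snoRNAs that share a host gene was set before its result was seen, but its 4th pair, Snora64 and Snora78, was added after the result for the other 3 was seen: pairs were first formed from identical host entries only, which left out a snoRNA listed under 2 hosts. Pairs from 1 host gene were positively correlated over the 7 group means: r was 0.931 for Snora16a and Snora44 (Snhg12), 0.863 for Snora34 and Snora2b (Kansl2), 0.711 for Snora64 and Snora78 (Rps2) and 0.578 for Snora17 and Snora43 (Snhg7). Their mean of 0.771 lay at the 99.95 percentile of 10000 random pairings (median 0.159), and with the first 3 pairs the mean of 0.791 lay at the 99.9 percentile. Correlation does not measure the size of changes, which differed within pairs. In the same order, ranges over the 4 cell types were 1.64 and 2.01-fold, 1.03 and 1.73-fold, 5.93 and 2.33-fold, and 1.37 and 5.12-fold. Host gene transcription may set part of the level of these snoRNAs, a hypothesis that rests on 4 pairs and 7 groups without host gene levels.

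Median absolute log2 differences from ESCs at day 0 were 0.213 for set A, 0.492 for set B and 0.564 for cardiomyocytes over 72 features. The most abundant feature of each sample took 14.5% to 17.3% of counts in cardiomyocytes and 7.84% to 12.2% in the other groups.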
